A study of Mus musculus with 4 samples.

How the data were processed

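Bulk RNA was sequenced from acute myeloid leukaemia grown in mice. Per the labels' protocols, leukaemia cells carrying NRASG12V and the Mll-AF9 fusion were injected into SCID/Beige mice, a strain with immune defects, and the mice were aged for 20 days, to a white blood cell count above 100000 per microlitre. Doxycycline, which switches NRASG12V expression off in this model, was injected at time 0 and then given in drinking water. The labels name 4 samples: 1 with NRASG12V on and 3 with it off, at 48 h, 72 h and 96 h. Each group holds 1 library. No sample is named that received doxycycline while NRASG12V stayed on. Effects of the drug or of elapsed time therefore cannot be told apart from the switch. The labels do not state which tissue was harvested, whether each library came from a separate mouse, or when the on sample was taken. RNA was extracted with a Qiagen RNeasy kit and libraries were made by the standard Illumina RNA-seq procedure, per the labels' protocols.

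The authors deposited FPKM values (fragments scaled to transcript length and to the mapped total) for 23235 genes in 4 tables. Each of 3 tables pairs the on library with the off library of 1 time, and the fourth pairs it with a combined off value. TopHat2 2.0.4 and Cuffdiff were used with genome build mm9, per the submitters' processing notes; the Cuffdiff version, annotation, read length and strand setting are not given in the sources used here. The column headed 0 hours was taken as the on library. Each deposited table was scaled separately: the on column of each was that of the others times 1 factor per table, and 99.9% of its values above 0 agreed within 0.1% after that factor in each of the 3 tables of 1 time (99.5% in the combined table). The 4 libraries were put on a common scale through that column, so any level set across times rests on this step. The deposited combined off value followed the mean of the 3 off libraries within 5% after 1 factor of 1.03 for 99.99% of the genes with a mean of at least 1 FPKM and a combined value above 0; 4 abundant globin genes, listed at 0 in the combined column, lie outside that comparison.

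FPKM hold no read counts, so the total depth of each library is unknown and no counting intervals can be given. The low values step with whole reads, and 1 read was worth 0.873, 0.963 and 0.842 times as much FPKM at 48 h, 72 h and 96 h as in the on library. Each off library thus held more reads per unit of FPKM, by a factor of 1.15, 1.04 and 1.19. These are relative depths only if the scaling followed the mapped totals, which the separate scaling of each table leaves open. An exact 0 in such tables can be a failed estimate. Of the genes reaching 20 FPKM in at least 1 library, 36 were listed at 0 in another, of which 33 were microRNA or small nucleolar RNA rows; the others were Hba-a1, Hba-a2 and Atp6v0c-ps2. Such genes are described by each library's value. Genes with near-identical copies, among them the globins, Ear11, Amd1, pseudogenes and ribosomal protein genes, are uncertain, since reads may be divided between copies.

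Changes were computed as log2((off FPKM + 1)/(on FPKM + 1)). A fold change on this log2(value + pseudocount) scale understates the change of genes with low values. At each time, genes reaching 1 FPKM in either library were counted as higher or lower when they differed at least 2-fold. With 1 library per group, these counts have no replicate check and no p-value. The overlap of the 3 times was set beside simulated libraries without effects that shared the on library (100 draws), and beside each off library put in the place of the on library. The 3 off libraries were also tested as 3 samples of the off state against the on library with limma 3.58.1 (statmod 1.5.0, R 4.3.3) on log2(FPKM + 1), with eBayes using trend and robust settings, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. This treats differences between the times as spread and assumes that the lone on library varies like the off libraries. Nothing says that the off libraries are separate animals, so these p-values measure only the spread between these samples. On simulated data for 11958 genes, the limma test recovered 52.6% of 500 genes changed 4-fold and 0.2% of 500 changed 2-fold, with 4 false calls among 268 calls. Few genes were changed in each simulated run, and noise was independent between genes. In the real data limma called 3227 genes, although only 1408 had a fitted change of at least 2-fold. The simulated rates therefore need not hold for these data.

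Before the data were examined, 32 gene lists were fixed for pathways, sample quality and other cell types; 769 of their 772 entries matched a gene. Each list's median was placed among 10000 random lists of the same size matched on mean expression, with a bootstrap interval over its members (2000 draws). The interval shows the spread among genes and is no replicate error. Over the 3 times, 30 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. A pan-leukocyte list and a second erythroid list were added later, for tests of cell makeup. Gene names are those of the deposited tables; older symbols were matched through the RefSeq table of assembly GRCm38.p6, and no coordinates were used because the builds differ. Tests of length and GC content used the transcripts of GENCODE M21 on GRCm38, looked up by symbol.

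The genes named follow a rule fixed before the data were examined. It takes Nras, Mll1 and Mllt3; per time, the 8 with the largest rise and the 8 with the largest fall among genes reaching 5 FPKM; the 12 with the largest mean rise and the 12 with the largest mean fall among those at least 2-fold changed at all 3 times; and up to 4 members of each list with the largest mean change. Unnamed gene models and short RNA rows were counted but not named, and some genes the rule takes are not reported here. Alternatives tried were pseudocounts of 0.1 and 5 FPKM, other filters on low FPKM, setting the median change to 0, leaving out short RNA rows or each off library, other limma settings, and other list statistics. Leaving out genes listed at 0, and setting list medians against the pan-leukocyte list, were chosen after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.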

Results

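The data describe RNA levels in NRASG12V and Mll-AF9 leukaemia before and after NRASG12V was switched off with doxycycline, in 4 libraries: on, and off for 48 h, 72 h and 96 h. The series' title ties NRASG12V to leukaemia self-renewal. The question put to these data is which transcripts differ once the oncogene is off, and from which time. Across genes, which are not independent replicates, log2 values of the on library correlated with those of the off libraries at 0.922, 0.919 and 0.898, and the off libraries with one another at 0.947 to 0.968. Depth is unknown beyond the relative reads per unit of FPKM above.

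Nras itself, the mouse gene of the switched oncogene, stood at 23.6 FPKM in the on library and at 16.5, 17.4 and 18.8 FPKM at 48 h, 72 h and 96 h. Its mean log2 change of -0.41 ± 0.09 (SD, n = 3 off libraries) did not pass the limma test (Benjamini-Hochberg adjusted p = 0.128). All 3 off libraries lay below the on library. The transgene is written in capitals, as a human gene would be, and reads from a human sequence may not all be assigned to mouse Nras, so this level is a weak check of the labels. Of the fusion's partner genes, Mllt3 (AF9) rose by 1.34 ± 0.33 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0083) and Mll1 by 0.58 ± 0.10 (adjusted p = 0.046; 0.193 without the 72 h library). FPKM per gene do not separate the fusion transcript from the normal genes.

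Over the 3 times, 13 of 16 primary granule genes, 13 of 21 genes of ERK signalling output and 16 of 27 glycolysis and hypoxia genes fell, and 18 of 20 erythroid and 17 of 35 interferon-stimulated genes rose. Each of these lists passed limma's camera test with the preset correlation (Benjamini-Hochberg), and none with an estimated one (adjusted p = 0.771 with an estimated correlation). In that order, the estimated correlations were 0.64, 0.19, 0.42, 0.61 and 0.78, above the preset 0.01. The p-values at the preset correlation may therefore be too small. The estimated version rests on 2 residual degrees of freedom, so its failure to pass a list decides little. Among the named genes that passed the limma test, the cadherin Cdh17 had the largest fall, with a mean log2 change of -4.84 ± 0.11. It went from 34.2 FPKM on to at most 0.322 FPKM off. Next came the small GTPase Gem (-4.07 ± 0.09) and the chemokine Ccl2 (-3.85 ± 0.16, SD, n = 3). They were followed by the neutrophil protease Ctsg (-3.68 ± 0.17), Spp1 (osteopontin, -3.55 ± 0.40), the basophil protease Mcpt8 (-3.42 ± 0.22), Ear11 (-3.42 ± 0.06), Dmkn (-3.40 ± 0.04), Prtn3 (-3.12 ± 0.11), Ccl9 (-3.09 ± 0.56) and Ms4a3 (-3.08 ± 0.27). The largest rises were those of the embryonic globin Hbb-y (4.57 ± 0.31), the tachykinin Tac2 (3.34 ± 0.66), Fn3k (3.06 ± 0.28), the interferon-induced Isg15 (3.04 ± 0.54) and Rsad2 (2.85 ± 0.20), the blood group gene Kel (2.81 ± 0.42), the haem synthesis enzyme Uros (2.78 ± 0.29) and Hbb-b1 (2.74 ± 0.65). Ccnb1ip1 (2.70 ± 0.13), the erythroid transcription factor Klf1 (2.59 ± 0.28), Abcg4 (2.57 ± 0.35) and Car1 (2.57 ± 0.47) completed the set. Each of these 23 genes passed the limma test, with Benjamini-Hochberg adjusted p from 4.77e-06 for Cdh17 to 0.0107 for Tac2. Atp6v0c-ps2, a pseudogene with a mean log2 change of -4.14 ± 2.03, did not (limma, Benjamini-Hochberg adjusted p = 0.323). It was at 38.4 FPKM on, 0.0015 FPKM at 48 h, 10.3 FPKM at 72 h and listed at 0 at 96 h.

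In all, limma called 3227 of 11958 genes, 1410 up and 1817 down (Benjamini-Hochberg adjusted p under 0.05), and 4955 genes had an unadjusted p under 0.05. With the median change set to 0, the split became 1738 up and 1240 down. The test compares 3 libraries with 1, so the on library has no replicate, and adding the slope of time as a covariate raised the count to 6024.

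The primary granule genes, made in early myeloid cells, fell together: 13 of 16 measured members fell, none rose and 3 did not pass (14 down adjusted over the list alone). Besides Ctsg, Prtn3 and Ms4a3, neutrophil elastase Elane fell by 3.01 ± 0.18, from 945 FPKM to 133, 114 and 104 FPKM. The list's median was -1.89 (limma camera, Benjamini-Hochberg adjusted p = 1.46e-08; adjusted p = 0.771 with an estimated correlation). Genes shared by leukocytes had a median of -0.76 over the same libraries. Of 26 later granule and neutrophil genes, 8 rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone. Mmp8 rose by 2.52 ± 0.43, the resistin relative Retnlg by 2.25 ± 0.41, Mmp9 by 1.76 ± 0.40 and the chemokine receptor Cxcr2 by 1.55 ± 0.44. At 48 h, 72 h and 96 h the list's median was 0.62, 0.49 and -0.13, and at 96 h 5 members were at least 2-fold higher and 6 lower. Over the 3 times it was 0.25 (limma camera, Benjamini-Hochberg adjusted p = 0.0457; adjusted p = 0.846 with an estimated correlation). Among monocyte and macrophage genes, 11 of 36 fell and 1 rose (12 and 1 adjusted over the list alone), and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.102; adjusted p = 0.846 with an estimated correlation). At 48 h, 72 h and 96 h the monocyte and macrophage medians were -0.21, -0.21 and -0.54, at percentiles 76.6, 49.55 and 0.03 of matched random lists. At 96 h, 15 members were at least 2-fold lower and 0 higher, and the pan-leukocyte median was -1.13. Trem2 fell from 37.4 FPKM to 5.19, 4.80 and 2.07 FPKM. The transcription factor Klf4 (-2.47 ± 0.31), the scavenger receptor Msr1 (-2.44 ± 0.43) and the clotting factor subunit F13a1 (-2.75 ± 0.53) fell too. F13a1 had a limma adjusted p (Benjamini-Hochberg) of 0.00217, and of 0.0630 without the 48 h library.

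Of 21 measured transcripts known to follow ERK activity, the MAPK branch downstream of Ras, 13 fell and none rose (15 down adjusted over the list alone). The ETS factor Etv4 fell by 2.67 ± 0.05, from 5.84 FPKM to at most 0.0926 FPKM, and the receptor Epha2 (-2.39 ± 0.11) and the early response genes Egr1 (-2.01 ± 0.02) and Fos (-1.97 ± 0.19) fell as well. The median was -1.04 (limma camera, Benjamini-Hochberg adjusted p = 9.57e-06; adjusted p = 0.771 with an estimated correlation). At 48 h, 72 h and 96 h it lay below that of the pan-leukocyte genes by 0.44 (95% bootstrap interval over genes -0.06 to 0.79), 0.24 (-0.33 to 0.89) and 0.04 (-0.49 to 0.54), intervals that include 0. The heat shock and handling list, which also holds Fos, had medians of -0.04, -0.63 and -0.71 at these times, the last 2 at percentile 0.17 of matched random lists, though the list's means there, -0.36 and -0.34, lay at percentiles 6.61 and 11.98; its member Jun fell by 1.36 ± 0.21.

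Glycolysis and hypoxia genes fell in 16 of 27 cases and rose in 2 (20 and 3 adjusted over the list alone). Pgam1 fell by 2.33 ± 0.38, the oxygen sensor Egln3 by 1.84 ± 0.19, Pfkp by 1.76 ± 0.19 and Pkm2 by 1.65 ± 0.49. The median was -1.03 (limma camera, Benjamini-Hochberg adjusted p = 8.47e-05; adjusted p = 0.771 with an estimated correlation), beside -0.76 for pan-leukocyte genes. The pan-leukocyte median minus this list's was 0.43 (95% bootstrap interval over genes -0.13 to 0.75), 0.25 (-0.30 to 0.69) and 0.15 (-0.50 to 0.60) at 48 h, 72 h and 96 h, intervals that include 0. Gapdh, often used as a reference gene, fell by 1.51 ± 0.20 and Pgk1 by 1.48 ± 0.21. Sterol and fatty acid synthesis genes fell in 11 of 29 cases and rose in 1 (13 and 1 adjusted over the list alone), among them Insig1 (-1.12 ± 0.12), Hsd17b7 (-1.05 ± 0.03) and Fdps (-1.02 ± 0.20). Their median was -0.42 (limma camera, Benjamini-Hochberg adjusted p = 0.0222; adjusted p = 0.771 with an estimated correlation), above the pan-leukocyte median. Of the Atf4 and amino acid supply genes, 9 of 32 rose and 2 fell (11 and 3 adjusted over the list alone). Trib3 rose by 2.01 ± 0.28 and asparagine synthetase Asns by 1.81 ± 0.29, whereas Ddit4 fell by 2.92 ± 0.64 and Cebpb by 1.85 ± 0.39. The median was 0.47 (limma camera, Benjamini-Hochberg adjusted p = 0.000834; adjusted p = 0.771 with an estimated correlation).

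Erythroid markers rose in 18 of 20 cases and none fell, with the same counts adjusted over the list alone. The median was 2.07 (limma camera, Benjamini-Hochberg adjusted p = 2.42e-11; adjusted p = 0.771 with an estimated correlation). Hbb-b1, an adult beta globin, stood at 736 FPKM on and at 3167, 4818 and 7748 FPKM at 48 h, 72 h and 96 h; Klf1 went from 24.3 to 130, 141 and 188 FPKM and the carbonic anhydrase Car1 from 38.4 to 170, 231 and 325 FPKM. The members that did not pass were the alpha globins Hba-a1 and Hba-a2, which were listed at 0 at 96 h. Globin genes other than alpha made up 2.06%, 6.75%, 10.5% and 11.9% of the summed FPKM outside short RNAs in the on, 48 h, 72 h and 96 h libraries. Megakaryocyte and platelet genes rose in 8 of 15 cases and fell in 1 (12 and 1 adjusted over the list alone). Gp6 rose by 1.38 ± 0.05, Vwf by 0.94 ± 0.03 and F2rl2 by 0.90 ± 0.11, while P-selectin, Selp, fell by 1.55 ± 0.11. The median was 0.65 (limma camera, Benjamini-Hochberg adjusted p = 7.39e-05; adjusted p = 0.771 with an estimated correlation).

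Interferon-stimulated genes rose in 17 of 35 cases and none fell (24 up and 1 down adjusted over the list alone). Isg15 went from 17.7 FPKM to 204, 99.5 and 176 FPKM and Rsad2 from 15.5 FPKM to 107, 110 and 139 FPKM; Oas3 rose by 2.25 ± 0.66 and Ifit3 by 2.04 ± 0.67. Without the 96 h library, Oas3 and Ifit3 no longer passed limma's test (Benjamini-Hochberg adjusted p = 0.176 and 0.197). Oasl2 (2.44 ± 0.81, adjusted p = 0.0759) and Rtp4 (2.38 ± 0.77, adjusted p = 0.0584) did not pass limma's test with Benjamini-Hochberg adjustment. The list's median was 1.10 (limma camera, Benjamini-Hochberg adjusted p = 2.74e-09; adjusted p = 0.771 with an estimated correlation). The erythroid median over the same libraries was 2.07. In the on library, 27 of the 35 interferon-stimulated genes reached 1 FPKM. The rest passed the filter through an off library, which favours a rise for them.

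**Figure D1:**
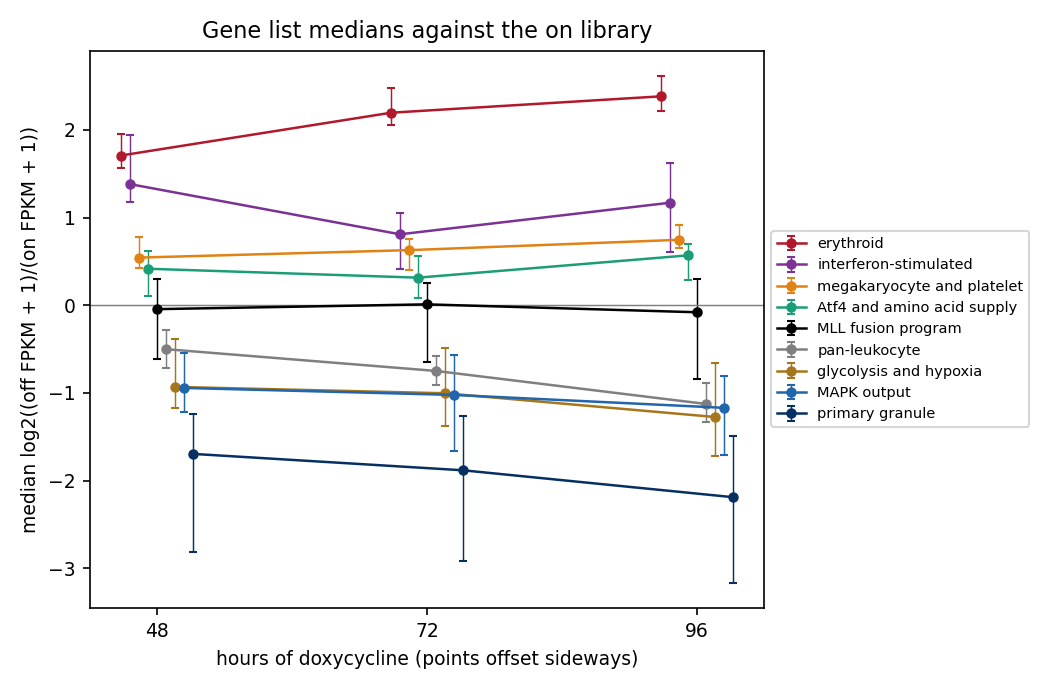
Median log2((off FPKM + 1)/(on FPKM + 1)) of 9 gene lists (vertical axis) against hours of doxycycline (horizontal axis), with 1 library per time; bars are 95% bootstrap intervals over the genes of a list. The erythroid median goes from 1.71 to 2.38 and the primary granule median from -1.69 to -2.19 between 48 h and 96 h, while the medians of the MLL fusion program, whose members go both ways, lie between -0.08 and 0.01 (between -0.01 and 0.11 with the median change of all genes set to 0, and at -0.52 at 96 h among members reaching 5 FPKM).

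Genes bound or held on by MLL fusion proteins went both ways. Of 18 measured, 5 fell and 4 rose (6 and 4 adjusted over the list alone). Mef2c fell by 1.42 ± 0.12, the kinase gene Cdk6 by 1.39 ± 0.22 and the homeobox gene Hoxa7 by 1.29 ± 0.08. The list did not pass limma's camera (Benjamini-Hochberg adjusted p = 0.890); its median was 0.04, its mean -0.15 and the direction of the test down. Among members reaching 5 FPKM the medians at 48 h, 72 h and 96 h were -0.12, -0.32 and -0.52, at percentiles 58.0, 19.4 and 6.75 of matched random lists. The pan-leukocyte median minus this list's was -0.48 (95% bootstrap interval over genes -0.91 to 0.04), -0.78 (-1.09 to -0.13) and -1.06 (-1.54 to -0.50) at 48 h, 72 h and 96 h. Random lists matched on expression had medians of -0.39, -0.38 and -0.24 for the pan-leukocyte list. For the MLL fusion list they had -0.06, 0.01 and -0.004, so part of the differences goes with expression level. Of 20 genes tied to Myb and leukaemia self-renewal, 5 fell and 2 rose (6 and 3 adjusted over the list alone). The repressor Gfi1 fell by 1.55 ± 0.36, the survival gene Bcl2 from 9.20 FPKM to 2.75, 3.08 and 2.04 FPKM and Cited2 by 1.27 ± 0.28, and Gfi1b, which is active in erythroid cells and megakaryocytes, rose by 1.41 ± 0.38. This list did not pass either (limma camera, Benjamini-Hochberg adjusted p = 0.454). For it the pan-leukocyte median minus the list's was -0.27 (-0.72 to 0.06), -0.58 (-0.98 to -0.17) and -0.87 (-1.34 to -0.44). Its matched random lists had medians of -0.20, -0.14 and -0.10. Among 18 stem and progenitor genes, 3 rose and 3 fell, also adjusted over the list alone; the blood-forming regulator Tal1, which erythroid cells use too, rose by 2.03 ± 0.28, while Cd34 fell by 1.93 ± 0.08 and Cd93 by 1.48 ± 0.28. The camera test gave an adjusted p of 0.475 for it (limma, Benjamini-Hochberg).

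Of 35 Myc targets and ribosome biogenesis genes, 6 fell and 2 rose (5 and 2 adjusted over the list alone), and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.124). The nucleolar genes Pes1 and Nop16 fell by 0.85 ± 0.08 and 0.79 ± 0.17; those that rose were the transferrin receptor Tfrc, abundant in erythroid precursors, by 2.19 ± 0.27, and Odc1 by 0.97 ± 0.22. Without the 72 h library, limma's Benjamini-Hochberg adjusted p was 0.0689 for Pes1, 0.0728 for Nop16 and 0.0844 for the mitotic gene Hmmr. DNA replication genes rose in 3 of 32 cases and none fell, also adjusted over the list alone: the cyclins Ccne1 by 1.34 ± 0.34 and Ccne2 by 1.09 ± 0.35, and the replication licensing factor Cdc6 by 1.25 ± 0.32. The median was 0.36 (limma camera, Benjamini-Hochberg adjusted p = 0.00406; adjusted p = 0.846 with an estimated correlation). Of 34 mitotic genes, Mki67 (1.18 ± 0.33) and Hmmr (0.85 ± 0.26) rose, none fell, and 0 passed adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.102). By time, the DNA replication medians were 0.03, 0.36 and 0.66 at 48 h, 72 h and 96 h, at percentiles 99.7, 100 and 100 of matched random lists. The mitotic medians were -0.13, 0.19 and 0.35, at percentiles 92.4, 99.96 and 99.98. The limma test counts such differences between times as spread. The erythroid median over these libraries was 2.07.

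**Figure D2:**
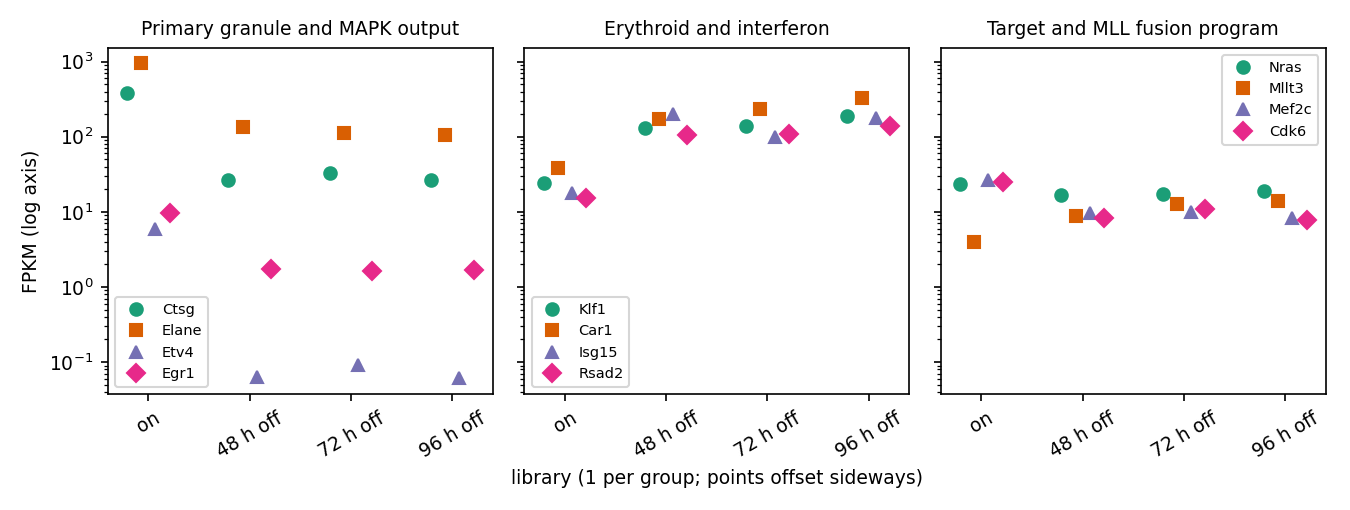
FPKM on a log axis (vertical) of 12 named genes in the on library and the 48 h, 72 h and 96 h off libraries (horizontal), 1 point per library. Elane and Ctsg stand lower in all 3 off libraries, Klf1, Car1, Isg15 and Rsad2 higher, and Nras lies between 16.5 and 18.8 FPKM off against 23.6 FPKM on.

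At 48 h, the first time sampled, Cdh17, Gem, Ctsg, Ccl2, Spp1, Mcpt8 and Ear11 were already among the 8 genes with the largest fall. Ctsg, for one, stood at 26.6 FPKM against 377 FPKM on. The largest rises at 48 h were in Hbb-y, from 16.8 to 326 FPKM, Fn3k, the granule protease Mmp8, from 22.7 to 156 FPKM, and 5 interferon-stimulated genes, Isg15, Oasl2, Rtp4, Oas3 and Ifit3. Ifit3 went from 0.425 to 8.29 FPKM. The interferon median was 1.38, above 100% of the matched random lists, the erythroid median 1.71 and the primary granule median -1.69. In all, 587 genes were at least 2-fold higher and 569 lower among 11739. Genes expressed in both libraries had a median change of -0.15, and with that set to 0 the split was 811 higher and 395 lower. A pseudocount of 0.1 FPKM gave 1830 genes and of 5 FPKM 531.

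At 72 h, the erythroid membrane skeleton gene Spna1 (alpha spectrin), at 144 FPKM against 18.7 FPKM on, and Kel, at 130 FPKM against 15.2 FPKM, entered the 8 largest rises beside Hbb-y, Tac2, Fn3k, Mmp8 and Rsad2. Amd1, which has near-identical copies, was at 5.83 FPKM at 72 h and at 0.0019 FPKM at 48 h, and did not pass the limma test over the 3 times (Benjamini-Hochberg adjusted p = 0.534). The falls were led by Cdh17, Gem, Ccl2, Mcpt8, Ctsg, Dmkn, Ear11 and Prtn3. The erythroid median was 2.20, the interferon median 0.81 and the MAPK output median -1.02. Of 11746 genes, 776 were at least 2-fold higher and 676 lower, and with the median change set to 0, 906 and 539. With a pseudocount of 0.1 FPKM the total went from 1452 to 2185 and with 5 FPKM to 686.

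At 96 h, the haem synthesis enzyme Uros (81.3 FPKM against 8.60 on), Hbb-b1 and Kel were among the 8 largest rises, with Hbb-y, Tac2, Fn3k, Isg15 and Rsad2. Besides the globin rows listed at 0 and Atp6v0c-ps2, the largest falls were in Cdh17, Gem, Ccl2, Spp1 (2.29 FPKM against 48.6 on) and Ctsg. The erythroid median was 2.38, the primary granule median -2.19, the glycolysis median -1.27 and the pan-leukocyte median -1.13, with 14 of 22 pan-leukocyte genes at least 2-fold lower. The interferon median was 1.17. Of 11729 genes, 867 were at least 2-fold higher and 957 lower, and with the median change set to 0, 988 and 805. A pseudocount of 5 FPKM brought the total of 1824 down to 916.

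Across the times, 436 genes were at least 2-fold higher and 421 lower in all 3 off libraries, 857 of 11965. With the median change set to 0, the split was 573 higher and 319 lower. Simulated libraries without effects shared the on library and were drawn with the spread between the off libraries. They gave 155 genes 2-fold changed at 1 time on average, against 1156 to 1824 observed. At all 3 times they gave 26.1 genes on average and 44 at most in 100 draws, and independent lists of the observed sizes would give 5.33. Part of the excess may come from the shared on library, which cannot be divided. With the 48 h, 72 h or 96 h library in the place of the on library, the count was 18, 12 and 34. Such counts are low whenever the off libraries resemble one another, whatever sets the on library apart. Between off libraries, 61 genes differed at least 2-fold from 48 h to 72 h, 78 from 72 h to 96 h and 131 from 48 h to 96 h. The count for all 3 times was 1385 with a pseudocount of 0.1 FPKM and 417 with 5 FPKM.

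In the authors' combined table, Hbb-y differed by 4.63 and Nras by -0.38 on the log2 scale, as the authors' values with no replicate error. The erythroid list had a median of 2.15 there, the interferon list 1.22, the primary granule list -1.83 and the MAPK output list -1.01. This table listed 4 abundant globin genes, Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, at 0 in its off column. Of 12015 genes, 824 were at least 2-fold higher and 631 lower. With the median change set to 0 the split was 935 higher and 523 lower, and a pseudocount of 5 FPKM gave 732 in all.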

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

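The differences between times in this part were not tested, since each time holds 1 library. The median of the late granule and neutrophil list was 0.62 at 48 h and -0.13 at 96 h, a difference of -0.75, with 0.49 at 72 h. The MHC class II list had a median of 0.12 at 48 h and -0.40 at 96 h, a difference of -0.52, with H2-DMb1 at 60.0 and 35.2 FPKM. The mitotic list went from -0.13 at 48 h to 0.35 at 96 h, a difference of 0.48, and its 48 h median was 0.02 with the median change of all genes set to 0. Hba-a1 stood at 11914 FPKM at 72 h and Hba-a2 at 424 FPKM, and both were listed at 0 at 96 h, when Hbb-b1 was at 7748 FPKM.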

How the results depend on the processing

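Leaving out genes listed at 0 and setting lists against the pan-leukocyte median were chosen after seeing the data. The 2-fold counts depended most on the pseudocount: with 5 FPKM, they numbered 531, 686 and 916 at 48 h, 72 h and 96 h, 417 at all 3 times and 732 in the combined table, and with 0.1 FPKM 1830 at 48 h, 2185 at 72 h and 1385 at all 3 times. A larger pseudocount shrinks the change of low genes by construction. The slope of time as a covariate raised the limma count to 6024 and took the Nras level, a change of -0.41, past the threshold (limma, Benjamini-Hochberg adjusted p = 0.0185; 0.0744 to 0.427 under its other alternatives); it leaves fewer residual degrees of freedom, and the cause was not tested. With an estimated correlation, 0 lists passed limma's camera, against 14 with the preset one, and the smallest adjusted p was 0.771; 15 lists had an unadjusted p under 0.05 with the preset correlation. Without 1 off library, limma called 2336 to 4169 genes and the all-time count was 934 to 1228. With the mean in place of the median, the Myc target and MHC class II lists at 48 h, the heat shock list at 72 h and 96 h and the T cell list at 96 h no longer stood outside the central 95% of random lists, and the monocyte list at 72 h and the mast cell list at 72 h and 96 h newly did. With a filter at 5 FPKM, the sterol list at 48 h and 96 h, the NK list at 48 h and the T cell list at 96 h no longer did, and the mast cell list at all 3 times and the Bcl2 relatives at 72 h and 96 h newly did. Against random lists not matched on expression, the DNA replication, sterol and MHC class II lists at 48 h no longer did. Newly outside were the ribosomal and respiratory chain lists at 48 h and 72 h and the reference genes at all 3 times. So were the Myc target list at 72 h and the mast cell list at 48 h. Of the main results, 67 alternatives stayed within 1.5 times the count or on the same side of the threshold.

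Against the pan-leukocyte median, the sterol list turned to 0.14, 0.25 and 0.74 at 48 h, 72 h and 96 h, the Myc target list to 0.028 at 48 h, the inflammatory list to 0.35 and 0.64 and the heat shock list to 0.12 and 0.42 at 72 h and 96 h, and the monocyte list to 0.59 at 96 h, because that median itself lies below 0. With 1 off library left out, the fitted change ran from -4.995 to 1.78 for Hba-a1 off against on and from -3.08 to 1.42 for Hba-a2 off against on, positive only without the 96 h library, which lists both at 0. Of 138 named genes, no other reversed. With no filter on low FPKM, 18 of them no longer passed limma's test. Unknown depth limits the low genes most.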

Other observations

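Chosen only after the result was seen were the tests of the erythroid rise against other host lists and against scaling, those of the interferon rise against the erythroid order, those of the on library's own properties, and both tests of the MAPK output list. The pan-leukocyte and second erythroid lists were drawn up after the granule fall and the erythroid rise were seen, and before the values of their own genes were. Other fixed lists held movements not yet described. Marker genes of endothelial and stromal cells rose in 7 of 20 cases and fell in 1, also adjusted over the list alone, led by the niche chemokine Cxcl12 (1.70 ± 0.15), Stab2 (1.05 ± 0.18), Kdr (1.03 ± 0.14) and Dcn (0.99 ± 0.28; SD, n = 3). The list's median was 0.42 at 48 h, 0.52 at 72 h and 0.0087 at 96 h, where it was -0.19 among members reaching 5 FPKM; over the 3 times it was 0.32 (limma camera, Benjamini-Hochberg adjusted p = 0.00463; adjusted p = 0.771 with an estimated correlation). NK cell markers rose in 3 of 15 cases and fell in 1 (5 and 1 adjusted over the list alone; limma camera, Benjamini-Hochberg adjusted p = 0.0238; adjusted p = 0.771 with an estimated correlation): Ncr1, Gzma and Eomes rose, while Nkg7, which the primary granule list also holds, fell by 1.45 ± 0.19. Without the 48 h library, Gzma and Eomes did not pass limma's test (Benjamini-Hochberg adjusted p = 0.0507 and 0.0566), nor did Eomes without the 96 h library (0.0578). T cell markers rose in 3 of 7 cases and fell in 1 (4 and 1 adjusted over the list alone), with Cd3d up by 1.27 ± 0.42 and Cd5 down by 0.99 ± 0.20, and had a median of 0.58 (limma camera, Benjamini-Hochberg adjusted p = 0.0614). Mast cell and basophil markers had a median of 0.26 and a mean of -0.44; 4 of 10 fell and 2 rose (4 and 3 adjusted over the list alone), with Mcpt8 and Prss34 down. Among the 4 members reaching 5 FPKM the medians were -1.36, -1.72 and -1.67 at 48 h, 72 h and 96 h, at percentiles 0.11, 0 and 0.06 of matched random lists (for all members, limma camera, Benjamini-Hochberg adjusted p = 0.927). Only 6 NK cell and 5 T cell markers reached 1 FPKM in the on library. The others tested passed the filter through an off library, which favours a rise for them. Eomes stood at 0.414 FPKM on and at 1.71, 0.914 and 1.24 FPKM at 48 h, 72 h and 96 h. Ncr1 stood at 0.715 FPKM on and at 2.77, 3.24 and 3.20 FPKM at these times. B cell and hepatocyte lists had 4 and 2 measured members, with medians of 0.10 and 0.09. Among inflammatory genes, 8 of 25 fell and 4 rose (11 and 4 adjusted over the list alone); Il1b rose by 2.13 ± 0.38 and Ccl3 fell by 1.90 ± 0.39 (limma camera, Benjamini-Hochberg adjusted p = 0.160).

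Ribosomal protein genes, which share reads with pseudogenes, had a median of -0.49 and 0 of 34 passed limma, also adjusted over the list alone, with 7 at an unadjusted p under 0.05 (limma camera, Benjamini-Hochberg adjusted p = 0.00129; adjusted p = 0.846 with an estimated correlation). The ribosomal median was -0.23 (-0.27 to -0.20) after regression on length, GC content and expression, and lay at percentiles 8.05, 6.26 and 53.9 of expression-matched random lists at 48 h, 72 h and 96 h. Respiratory chain genes had a median of -0.32 and 1 of 33, Ndufb5, fell, with 0 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0457; adjusted p = 0.846 with an estimated correlation). The respiratory chain medians lay at percentiles 35.6, 40.6 and 88.9 of expression-matched random lists at the 3 times. The remaining lists did not pass limma's camera with Benjamini-Hochberg adjustment: p53 targets (adjusted p = 0.633; Btg2 up, Pmaip1 and Bax down), Bcl2 relatives (0.247; Bak1 down, Bcl2l1 up), Foxo targets (0.577; Gadd45a up, Pik3ip1 down; median 0.05, mean -0.10), lysosome genes (0.459; 9 of 30 down, among them Gpnmb, Gla and Ctsa, and 4 up, among them Ctsf; 11 and 6 adjusted over the list alone), MHC class II genes (0.746), heat shock and handling genes (0.538; Hsph1 up, Jun down) and reference genes (0.167; median -0.57). Without the 72 h library, limma's Benjamini-Hochberg adjusted p was 0.128 for Ndufb5, 0.0656 for Ctsf, 0.0825 for Bax and 0.0743 for Bcl2l1.

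With NRASG12V on against off, limma called 3227 genes, and with another library in the lone place at most 13. The real placement was the 1 of 4 with as many, and 4 placements cannot give a share under 0.05. With an off library in the lone place, the on library joins the other group and widens its spread. Low counts there follow whenever the on library differs for any reason, so they say nothing of the cause.

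For the rise of erythroid markers, the values argue against scaling between libraries as the whole cause. A scaling factor moves all genes of a library alike. Genes expressed in both libraries had median changes of -0.15, -0.09 and -0.07 at 48 h, 72 h and 96 h, beside erythroid medians of 1.71, 2.20 and 2.38. Setting these changes to 0 could only raise the erythroid medians, so that step is no separate test. The lowest of the 3 was then 1.93, with the globin rows listed at 0 left out. Host lists did not rise alike. The erythroid median exceeded that of megakaryocyte and platelet genes, the highest other host list, by 1.44 (95% bootstrap interval over genes 1.28 to 1.84). A lower share of leukaemic cells stays open. A host list would rise less where leukaemic cells also express its genes, which these libraries cannot show. A second list of 23 erythroid genes, sharing none with the first, had a median of 1.77 (1.73 to 2.05), so a larger share of erythroid cells in the off samples is a candidate explanation. All 20 erythroid markers were already at 1 FPKM or more in the on library, and the labels name no sort or gate. Whether it is a biological response to the loss of NRASG12V or the state of 1 on sample stays open as a hypothesis. Effects of doxycycline or of elapsed time cannot be told apart from that loss.

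Regression on length, GC content and expression explained 2.58% of the variance of the mean log2 change across genes, so it is a weak check. After it, the interferon rise kept a median of 1.12 (0.75 to 1.70). Its members moved by a median of -0.76 (-0.88 to -0.51) from 48 h to 72 h and -0.40 (-0.55 to -0.30) from 48 h to 96 h, against 0.56 (0.40 to 0.62) and 0.67 (0.63 to 0.72) for erythroid genes, which argues against a growing share of erythroid cells as the whole cause. Both steps share the 48 h library and the intervals cover genes only; from 72 h to 96 h the medians were 0.33 (0.14 to 0.59) and 0.14 (-0.0036 to 0.40), so a part stays open. A property of the on library cannot be told apart from the switch, since that group holds 1 library: the off medians span 0.57, less than the 0.81 that parts the nearest from the on library. An effect of NRASG12V loss may account for it but was not tested separately from doxycycline or elapsed time.

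The fall of primary granule genes exceeded that of pan-leukocyte genes by 1.13 (0.53 to 2.20), and at 96 h alone by 1.06 (0.32 to 2.05). This argues against dilution of leukocyte RNA by RNA of other cells as the whole cause. The comparison cannot address a changed mix of leukocytes, since they share the pan-leukocyte genes. The granule list kept -1.74 (-2.70 to -1.19) after the regression on length, GC content and expression, and the MAPK output list kept -1.07 (-1.32 to -0.49). For the MAPK output list dilution stays open, since the smallest difference, 0.042 at 96 h, has an interval from -0.49 to 0.54. A property of the on library cannot be told apart from the switch for the granule list either, whose off medians span 0.49. Loss of NRASG12V signalling is an untested biological explanation for both lists, and cannot be told apart from doxycycline or elapsed time.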
